A study of Mus musculus with 56 samples.

How the data were processed

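RNA from mouse keratinocytes, the main cell type of the epidermis, was measured on 2-colour arrays, with RNA of cells treated with transforming growth factor β1 (TGF-β1) and RNA of untreated cells of the same kind on each array. Per the labels' protocols, the cells were isolated from newborn mice and either kept as primary cultures or transduced with a retrovirus carrying the Ha-ras oncogene (called ras keratinocytes here). TGF-β1 was given at 1 ng/ml for 1, 6, 24 or 48 h. There were 50 arrays of Balb/c cells and 6 arrays of Smad3 wild type and knockout cells at 48 h. Smad3 is a transcription factor that carries the TGF-β signal to the nucleus.

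The deposited values are 1 log ratio per probe and array, 9596 probes on 56 arrays with no missing value. They were used as log2 ratios: the base is not stated in the sources used here, and sizes beyond 10 rule out base 10. The scanning, background correction, filtering and normalization by the authors are not given in the sources used here. Medians of the deposited log2 ratios lay between -0.146 and 0.02 over the arrays, so the values had been brought near a common centre before deposit. Per the labels, channel 1 held untreated and channel 2 treated RNA, and the treated RNA carried Cy5 on 49 arrays and Cy3 on 7 arrays named as reversed. The direction, treated over untreated, is likely from the channel order and was checked on the list of TGF-β and SMAD target genes. Spot brightness was not used here, so the signal behind each ratio is unknown and the number of arrays limits the precision.

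Whether the authors had turned the sign of the 7 reversed arrays is not stated. A rule set before the data were examined correlated each of the 5 reversed Balb/c arrays with the mean of the other arrays of its group over all probes. A median correlation over 0.1 would have kept all 7 as deposited, one under -0.1 would have turned them, and one between left them out. The median was 0.0512, so the 7 arrays were left out, although the 2 reversed knockout arrays, which the rule did not use, correlated at 0.479 and 0.403 with the other array of their group. This left 1 knockout array per cell type. With no reversed array in use, the planned dye term was dropped because the remaining 49 arrays all have the same orientation. A bias of a gene towards 1 dye therefore stays in every response, while in a difference between responses it cancels if it is constant. The planned fits without a dye term and with Cy5 arrays alone became identical to the one reported, and both planned filters on missing values had nothing to remove.

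Probes were named from the platform annotation, with symbols updated through Entrez IDs: 7486 probes had 1 gene symbol, 483 had several and 1627 had none listed, and 7395 of the first matched the RefSeq table. Probes of 1 symbol were averaged per array, which joined several probes for 631 genes, and other probes were kept unnamed. This gave 8905 features, 6795 of them named genes. Each array was centred on its median, and the features were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all groups together, so that all groups share 1 estimate of the spread. Each response is a group mean tested against 0, and contrasts gave ras minus primary at each time, 48 h minus 6 h in each cell type, and Smad3 knockout minus wild type. Tests were two-sided, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 over the 8905 features. The arrays behind the responses at 1, 6, 24 and 48 h were 6, 7, 6 and 3 for primary cells and 6, 7, 6 and 4 for ras cells. The series description speaks of several arrays per timepoint sample, dye swaps among them, so arrays of a group may be technical repeats, and p-values then measure only the spread between arrays.

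Gene lists, 33 in all with at least 4 measured members, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 between genes, with adjustment over 264 tests for the responses, 132 for the ras minus primary differences and 99 for the other contrasts. Camera with an estimated correlation was the alternative. Of 68 response calls 4 held with an estimated correlation, of 18 difference calls 1 held, and of 25 other calls 4 held. The single genes named are the 4 largest rises and falls of each response among called genes with the same sign on every array of the group, the 3 largest each way of the ras minus primary and 48 h minus 6 h contrasts, the 5 largest each way of the Smad3 contrast, the 8 largest Balb/c effects shown per cell type on Smad3 arrays, the design genes Smad3 and Tgfb1, and members of the lists. This rule was also set before the data were examined. Which list members serve as examples was decided after their values were seen, and genes named in all called differences beyond the 3 largest were also chosen after their values were seen.

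The fit was tested on simulated data made from the residuals of the real arrays. The sign of each residual was drawn at random for each feature and array, which removes links between genes. With no gene changed, 20 simulated sets gave a median of 78 calls for primary cells at 48 h, 93 for ras cells at 24 h and 43 for ras cells at 48 h, but 1.5 for primary cells at 24 h and 0 for ras cells at 6 h. Some groups thus gave calls with no gene changed, the cause was not tested, and counts are given beside the simulated ones. In some comparisons the real count lay below the lowest of the 20 simulated sets. It was 1 against 6 for primary cells at 6 h and 18 against 52 for ras minus primary at 48 h. The simulated counts are therefore no sure level for data without change. With 200 changed genes, changes of 1 on the log2 scale were found for 82.1% of genes in primary cells at 24 h, 84.9% in ras cells at 6 h, 65.6% in ras cells at 24 h, 58.9% in primary cells at 48 h and 73.6% in ras cells at 48 h. False calls among unchanged features of the same simulated sets numbered 17, 17, 116, 111 and 84 in this order.

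Alternatives were deposited values without centring, arrays scaled to 1 median absolute deviation, single probes, array weights, each comparison fitted on its own groups, the replicate number or the block of upload numbers as a random block, equal weight for both dye orientations, and leaving out each array. After seeing the data 5 more were added: all arrays with the reversed ones turned, with and without a dye term; all arrays as deposited with a dye term; values beyond 4 in size as missing; and leaving out the 2 widest arrays. Turning was applied to all 7 reversed arrays, the 2 knockout ones among them, although these correlated positively with their partners as deposited. They also entered the dye term of the turned fit. Equal weight averages the mean of the Cy5 arrays with that of the reversed arrays as deposited. If the authors had not turned the reversed arrays, a true response then cancels by construction. A dye term fitted to them as deposited can take up such a response. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.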

Results

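The data follow the response of newborn mouse keratinocytes to TGF-β1, a growth factor that arrests epithelial cells and induces matrix genes, with and without a ras oncogene. Each array gave the log2 ratio of treated over untreated RNA of the same cell type. Primary Balb/c keratinocytes were represented by 6, 7, 6 and 3 arrays at 1, 6, 24 and 48 h, and ras keratinocytes by 6, 7, 6 and 4, after 7 arrays of the opposite dye orientation were left out. The Smad3 wild type and knockout cells had 1 such array for each genotype and cell type at 48 h. The SD of the values ranged over the 56 arrays from 0.194 to 1.81, and ras 24 h replicate 1 (SD 1.81) and primary 6 h replicate 1 (SD 1.68) were the widest. Values below are mean log2 ratios with the standard error (SE) of the fit, and the SD between arrays where given. Upward values, treated over untreated, are likely from the channel order, and the list of 25 TGF-β and SMAD target genes had a positive median in all 8 responses (0.11 to 0.39).

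Features called at 1, 6, 24 and 48 h numbered 1, 1, 121 and 766 in primary cells and 7, 154, 936 and 312 in ras cells. Named genes among them were 1, 1, 102 and 621 in primary and 7, 130, 696 and 253 in ras cells. Counts of called genes outside the gene lists take in unnamed probes throughout. In simulated data with no change the same groups gave medians of 11.5, 13.5, 1.5 and 78 in primary cells and 4, 0, 93 and 43 in ras cells. These are no sure level for unchanged data, since the real counts of primary cells at 1 h and 6 h lay below the lowest simulated ones (2 and 6). The calls depended on the spread shared by all groups: fitted on its own arrays alone, each group gave 0, 0, 10 and 0 calls in primary cells and 0, 137, 3 and 0 in ras cells with limma, while unadjusted p under 0.05 in the shared fit was reached by 478, 839, 900 and 1961 and by 626, 1059, 2193 and 1671 features. With reversed arrays turned and a dye term, 18 genes were up and 308 down in primary cells at 24 h and 308 up and 406 down at 48 h. In ras cells 9 were then up and 79 down at 1 h, 31 up and 121 down at 24 h and 16 up and 25 down at 48 h.

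**Figure D1:**
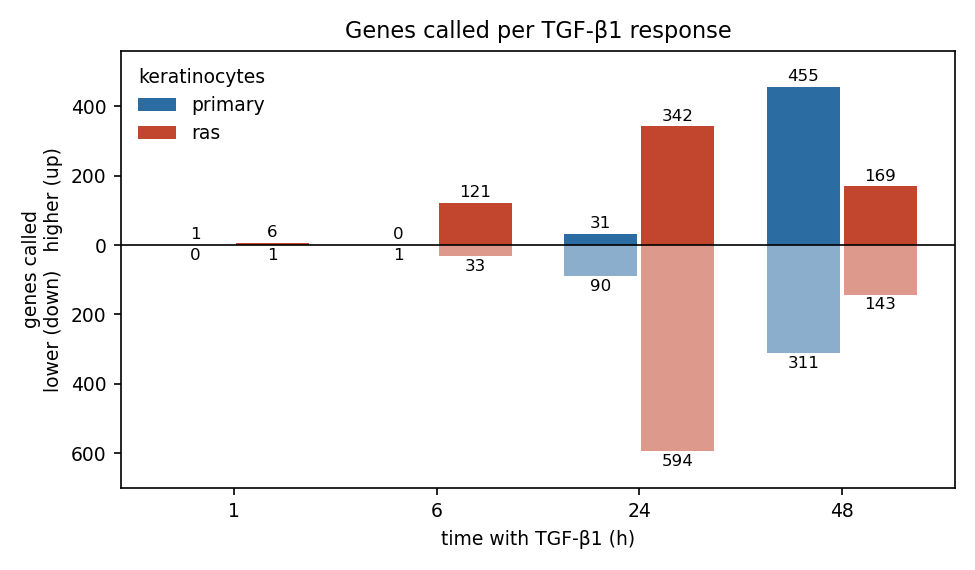
Number of features (named genes and unnamed probes) called higher (bars above 0) and lower (bars below 0) after TGF-β1 against the time of treatment in hours, for primary and ras keratinocytes. In the reported fit primary cells had the most calls at 48 h (455 up, 311 down) and ras cells at 24 h (342 up, 594 down). The time with the most calls in ras cells depended on the processing. Without ras 24 h replicate 1 the 24 h count was 273, against 312 at 48 h in the reported fit.

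After 1 h the called genes were few and were mostly early targets of TGF-β signalling. In primary cells Klf10, a zinc finger transcription factor induced early by TGF-β, rose by 0.84 (SE 0.15, SD 0.46, n = 6), and it was the only call (adjusted p = 0.0225, not called with upload blocks as a random term). In ras cells 6 genes rose and 1 fell. Skil, which encodes a SMAD co-repressor, rose by 1.33 (SE 0.22, adjusted p = 0.00237), and Smad7, the inhibitory SMAD, rose by 1.16 (SE 0.23). F3, which encodes tissue factor, rose by 1.22 (SE 0.24), Bhlhe40, a transcriptional repressor, by 1.10 (SE 0.22) and Klf10 by 0.76 (SE 0.15), while the immediate early gene Ier3 fell by 0.95 (SE 0.18). Of the 25 TGF-β and SMAD target genes, 1 rose in primary cells (6 adjusted over the list alone) and 4 in ras cells (7 adjusted over the list alone). The list was called higher in both cell types, with medians of 0.18 and 0.17, but adjusted p = 0.0876 and 0.0904 with an estimated correlation. Members below the threshold in primary cells were Skil at 1.02 (SE 0.22) and Smad7 at 0.98 (SE 0.23), and Myc stood at -0.97 (SE 0.35) in primary and -1.54 (SE 0.35) in ras cells. The single primary call is fewer than unchanged simulated data gave, 7 lies within the simulated range of 0 to 13 for ras cells, and with arrays scaled to 1 spread the ras split was 11 up and 6 down, and with array weights 19 up and 72 down. The primary count was 0 without any of replicates 3, 4, 5 or 6, and the ras count was 0 without replicate 2, 1 without replicate 4 or 6 and 2 without replicate 5. Skil lost its call without replicate 2 (adjusted p = 0.0682), and Smad7, F3, Bhlhe40, Klf10 and Ier3 lost theirs without 3 or more single arrays (adjusted p up to 0.184, 0.143, 0.157, 0.182 and 0.132).

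At 6 h ras keratinocytes had 121 genes up and 33 down, and 38 up and 68 down with reversed arrays turned and a dye term. Clu, the extracellular chaperone clusterin, rose by 2.12 (SE 0.32, SD 0.76, n = 7, adjusted p = 0.000212), a 4.35-fold change. Pdgfb, a platelet-derived growth factor chain, rose by 1.45 (SE 0.23), F3 by 1.41 (SE 0.22) and the TGF-β-induced matrix protein gene Tgfbi by 1.47 (SE 0.36). The neutrophil chemokine gene Cxcl5 fell by 1.77 (SE 0.31), the chemokine gene Ccl20 by 1.27 (SE 0.27), the serine protease gene Tmprss4 by 1.41 (SE 0.36) and the phosphatase gene Ptpn13 by 0.81 (SE 0.19). In primary cells the only call was Klf5, a transcription factor of proliferating epithelium, which fell by 0.90 (SE 0.16, adjusted p = 0.0111, not called with upload blocks as a random term) and lies outside the naming rule, so that it was chosen after its value was seen. Primary 6 h replicate 4 ran opposite to the other 6 arrays of its group for Clu (-1.78), Csf1 (-1.61), Skil (-0.84) and Timp1 (-0.77), genes positive on all others. Over all features its correlation with the mean of the others was 0.0147, against -0.0678 to 0.242 for the other arrays. Without it 4 genes were up and 5 down, and with its sign exchanged 25 were called.

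A coordinated group at 6 h was that of integrins, focal adhesion and the actin cytoskeleton. Of its 31 measured members 30 had positive values in ras cells, 7 rose (17 adjusted over the list alone) and 0 fell, and the list median was 0.38 (adjusted p = 5.48e-15, and adjusted p = 0.0436 with an estimated correlation). Rhob, a small GTPase, rose by 0.96 (SE 0.17), Pdlim7, an actin-associated adaptor, by 0.99 (SE 0.20), Tes, a focal adhesion protein gene, by 0.75 (SE 0.16) and the smooth muscle actin gene Acta2 by 0.66 (SE 0.14). Among the TGF-β and SMAD target genes 10 rose (12 adjusted over the list alone), including Skil by 0.96 (SE 0.20) and Cdkn2b, which encodes the cell cycle inhibitor p15, by 0.89 (SE 0.20); the list was called with a median of 0.22, and adjusted p = 0.0904 with an estimated correlation. Of 26 MYC and ribosome biogenesis genes 4 fell (6 adjusted over the list alone), among them Myc by 1.18 (SE 0.32) and the spermidine synthase gene Srm by 0.64 (SE 0.11), and adjusted p = 0.0876 with an estimated correlation. The basement membrane gene Lamb3 rose by 1.02 (SE 0.18) and Snai2, a repressor of epithelial genes, by 0.70 (SE 0.15). In primary cells at 6 h the same MYC list was called lower with 0 members called (median -0.17, adjusted p = 0.262 with an estimated correlation; limma called 839 features at an unadjusted p under 0.05). The ras count was 86, 85, 98, 102 and 62 without replicates 1, 2, 3, 7 and 8 in turn, and 98 with upload blocks as a random term. It rose to 1203 with array weights, 378 with arrays scaled to 1 spread and 240 without the 2 widest arrays. The primary count was 0 without replicate 1, 3, 6 or 7 and 9 without replicate 4, and 5 up and 13 down with arrays scaled to 1 spread. Calls of Tgfbi, Tmprss4, Ptpn13, Ccl20, Cdkn2b, Myc and Klf5 ended without at least 1 single array, with adjusted p up to 0.0983, 0.222, 0.0632, 0.0511, 0.056, 0.26 and 0.208.

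At 24 h some genes of terminal differentiation and of cell division fell in both cell types. Of their lists, only differentiation in primary cells was called with an estimated correlation. In primary cells 31 genes rose and 90 fell. Sprr2a1 and Sprr1a, which encode cornified envelope precursors, fell by 2.45 (SE 0.18, SD 0.66, n = 6, adjusted p = 1.9e-12) and 1.71 (SE 0.23), the fatty acid binding protein gene Fabp5 by 2.05 (SE 0.20), and Il1f5, an interleukin 1 family antagonist gene, by 1.81 (SE 0.27). Clu rose by 2.18 (SE 0.34, SD 0.75), the macrophage growth factor gene Csf1 by 1.53 (SE 0.27), the transcription factor gene Sox11 by 1.41 (SE 0.28) and Pdgfb by 1.15 (SE 0.25). In ras cells 342 genes rose and 594 fell. Clu rose by 2.86 (SE 0.34, SD 1.22, n = 6, adjusted p = 5.31e-07), Ctla2a and Ctla2b, which encode cysteine protease inhibitors, by 2.18 (SE 0.24) and 1.94 (SE 0.23), and the mitochondrial GTPase gene Mtg2 by 1.45 (SE 0.15).

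Of the 13 measured epidermal differentiation genes 4 fell and 0 rose in primary cells at 24 h (6 fell adjusted over the list alone), and 5 fell in ras cells (5 adjusted over the list alone). In ras cells these included Fabp5 by 1.56 (SE 0.20), Sprr1a by 1.42 (SE 0.23) and periplakin, Ppl, by 0.81 (SE 0.13). The list was called lower with medians of -0.51 and -0.37, and adjusted p = 0.000319 and 0.0876 with an estimated correlation. Of 43 genes of mitosis and G2/M, 9 fell in primary cells (23 adjusted over the list alone) and 19 in ras cells (25 adjusted over the list alone), with 0 rising. Birc5, which encodes survivin, fell by 1.55 (SE 0.27) and 1.26 (SE 0.27), the proliferation marker Mki67 by 0.82 (SE 0.18) in primary cells, and in ras cells the mitotic kinesin gene Kif20a by 1.46 (SE 0.25) and the topoisomerase gene Top2a by 1.05 (SE 0.21). Of 39 genes of DNA replication and S phase, 5 fell in primary and 7 in ras cells (10 and 8 adjusted over the list alone), among them the replicative helicase gene Mcm5 by 1.01 (SE 0.16) and 0.69 (SE 0.16). With an estimated correlation the mitosis list had adjusted p = 0.0788 and 0.0904, and the S phase list adjusted p = 0.11 and 0.432, in primary and ras cells.

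Some matrix genes rose at 24 h, but with an estimated correlation their list was not called in either cell type. Of 42 extracellular matrix genes 3 rose in primary cells (10 adjusted over the list alone) and 8 rose and 1 fell in ras cells (8 and 1 adjusted over the list alone). In ras cells the collagen genes Col18a1 and Col4a2 rose by 1.04 (SE 0.19) and 0.90 (SE 0.19), the matrix glycoprotein gene Sparc by 0.95 (SE 0.19), and the protease genes Plau and Mmp2 by 0.91 (SE 0.19) and 0.63 (SE 0.14). The matrix list medians were 0.22 and 0.30, with adjusted p = 0.149 and 0.368 with an estimated correlation. All 12 cholesterol synthesis genes had negative values in primary cells, with 0 called (4 adjusted over the list alone), a median of -0.48 and adjusted p = 0.137 with an estimated correlation; limma reached an unadjusted p under 0.05 for 900 features in this response. The 4 largest falls in ras cells, Ppat (-3.72, SD 4.86), P2ry1 (-3.50, SD 4.60), Klhdc7a (-3.48, SD 4.73) and Herc3 (-3.42, SD 4.76), ranged down to -10.3 on single arrays, and their calls ended without replicate 1 or 3 (adjusted p up to 0.114, 0.198, 0.226 and 0.168), that of P2ry1 also without replicate 5. The call of Mcm5 in ras cells ended without replicate 6 (adjusted p = 0.0559). The primary count fell to 60 without replicate 6, with the calls of Sox11 and Pdgfb lost (adjusted p = 0.0679 and 0.131), and the ras count fell to 273 without replicate 1 and 505 with upload blocks as a random term. With array weights the counts were 835 in primary and 562 in ras cells, the latter as 290 up and 272 down.

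**Figure D2:**
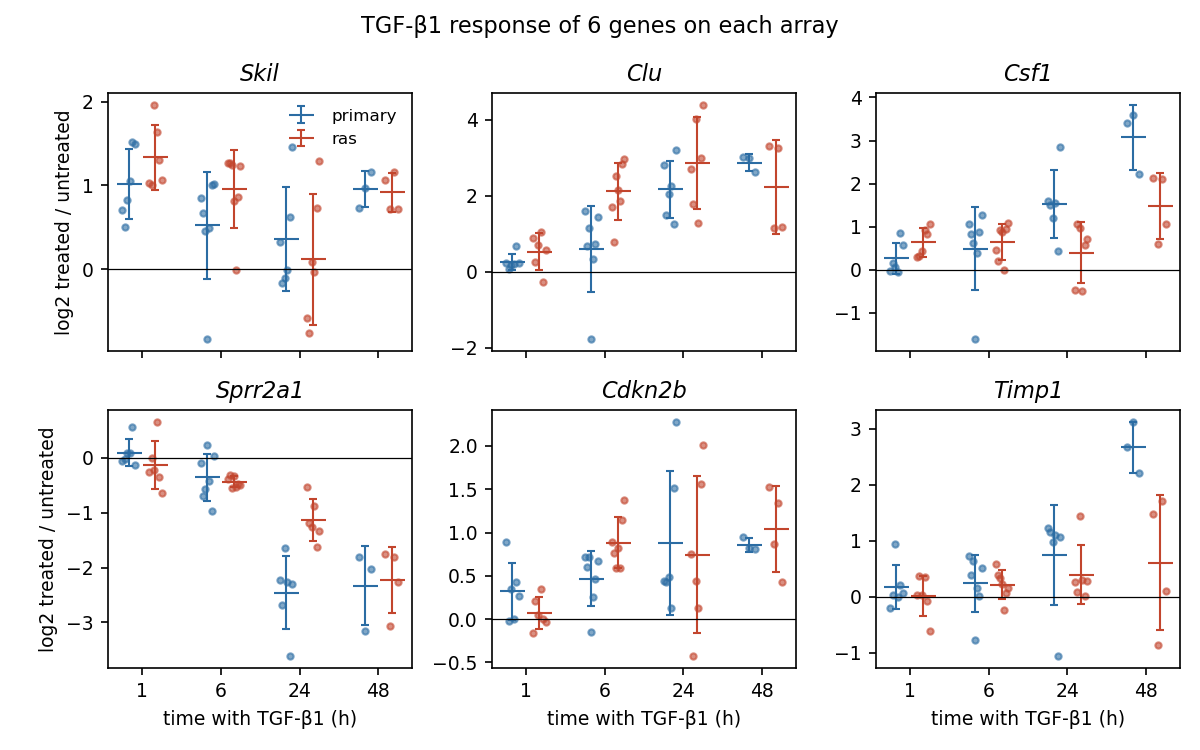
Log2 ratio of treated over untreated RNA on each array (points) with mean and SD (lines with bars) against hours of TGF-β1, for 6 genes in primary and ras keratinocytes. Clu rose in both cell types at 24 h and 48 h, while Sprr2a1 fell to -2.45 in primary and -1.14 in ras cells at 24 h.

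At 48 h matrix and mesenchymal genes rose in primary keratinocytes, with 455 genes up and 311 down overall. Ccl7, a monocyte chemokine gene, rose by 3.07 (SE 0.27, SD 0.73, n = 3, adjusted p = 5.46e-10), Csf1 by 3.07 (SE 0.38), Clu by 2.87 (SE 0.48) and the G protein subunit gene Gng2 by 3.58 (SE 0.56), the last between 0.83 and 7.95 on single arrays. Defb1, an epithelial defensin gene, fell by 3.34 (SE 0.40). The falls of 2410022M11Rik (-3.75), Rab11fip4 (-3.19) and Evx2 (-3.18) ranged over the 3 arrays from -7.70 to -0.27, -7.55 to -0.58 and -7.58 to -0.28, and their calls ended without 1 of them (adjusted p = 0.347, 0.75 and 0.0741 without replicates 1, 2 and 1).

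Of the 42 extracellular matrix genes 17 rose and 0 fell in primary cells at 48 h (22 up and 2 down adjusted over the list alone). The protease inhibitor gene Timp1 rose by 2.66 (SE 0.34), the elastic fibre gene Fbln5 by 2.63 (SE 0.37), the proteoglycan gene Bgn by 2.13 (SE 0.28) and Lox, which encodes a collagen cross-linking enzyme, by 1.90 (SE 0.26). Of 16 mesenchymal markers 6 rose (8 adjusted over the list alone), including S100a4 by 2.38 (SE 0.30), N-cadherin, Cdh2, by 1.94 (SE 0.34), Mmp2 by 1.83 (SE 0.20) and the transcription factor gene Twist1 by 1.28 (SE 0.21). The medians were 0.65 and 1.22, and adjusted p = 0.0802 for the matrix and 0.0436 for the mesenchymal list with an estimated correlation. Markers of other cell types moved with these groups: of 10 fibroblast markers, 6 of which also stand in another list, 3 rose (3 adjusted over the list alone), namely Col1a2 by 1.83 (SE 0.47), Mfap5 by 1.77 (SE 0.21) and Twist1. The fibroblast list was called with a median of 0.23, and adjusted p = 0.213 with an estimated correlation. Of 18 immune cell markers 3 rose, Lyz2 by 2.58 (SE 0.25), Tyrobp by 1.01 (SE 0.23) and Fcer1g by 0.77 (SE 0.19), and Cd8a fell by 1.75 (SE 0.51), while the list was not called (adjusted p = 0.235). The calls of Col1a2, Tyrobp and Fcer1g ended without replicate 2 (adjusted p up to 0.259, 0.0658 and 0.346), and that of Col1a2 also without replicate 1.

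In ras cells at 48 h 169 genes rose and 143 fell. Clu rose by 2.23 (SE 0.42, SD 1.23, n = 4, adjusted p = 0.00231), Csf1 by 1.48 (SE 0.32), Ccl7 by 1.42 (SE 0.24) and the adaptor gene Bcar1 by 1.69 (SE 0.34). Sprr2a1 fell by 2.23 (SE 0.22, SD 0.61), and Syt9, Clspn and Hif1a stood at -2.47, -2.25 and -2.25 with SDs of 3.28, 2.29 and 3.21. Of the 42 matrix genes 6 rose (12 adjusted over the list alone), among them Fbln2 by 1.40 (SE 0.26), and adjusted p = 0.262 with an estimated correlation. The immune cell marker Lyz2 rose as well, by 0.96 (adjusted p = 0.00893). Of the 13 epidermal differentiation genes 5 fell (7 adjusted over the list alone), including Fabp5 at -1.97 (SE 0.24) and Sprr1a at -1.85 (SE 0.29), with a median of -0.71 and adjusted p = 0.00469 with an estimated correlation. In primary cells 6 of the 13 fell (7 adjusted over the list alone), and adjusted p = 0.062 with an estimated correlation. Mitotic genes fell in ras cells, 6 of 43 (18 adjusted over the list alone), including the kinesin gene Kif4 by 1.44 (SE 0.26), and adjusted p = 0.213 with an estimated correlation. The alarmin gene Il33 fell in both, to -1.93 (SE 0.32) in primary and -2.02 (SE 0.28) in ras cells. The primary count was 439 without replicate 1 and 279 without replicate 2, and the ras count was 54 without replicate 1, 105 without replicate 3, 491 without replicate 4 and 111 with upload blocks as a random term. Without single arrays the calls of Clu, Csf1, Bcar1, Syt9, Clspn and Hif1a in ras cells ended (adjusted p up to 0.0519, 0.104, 0.0737, 0.368, 0.342 and 0.683).

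**Figure D3:**
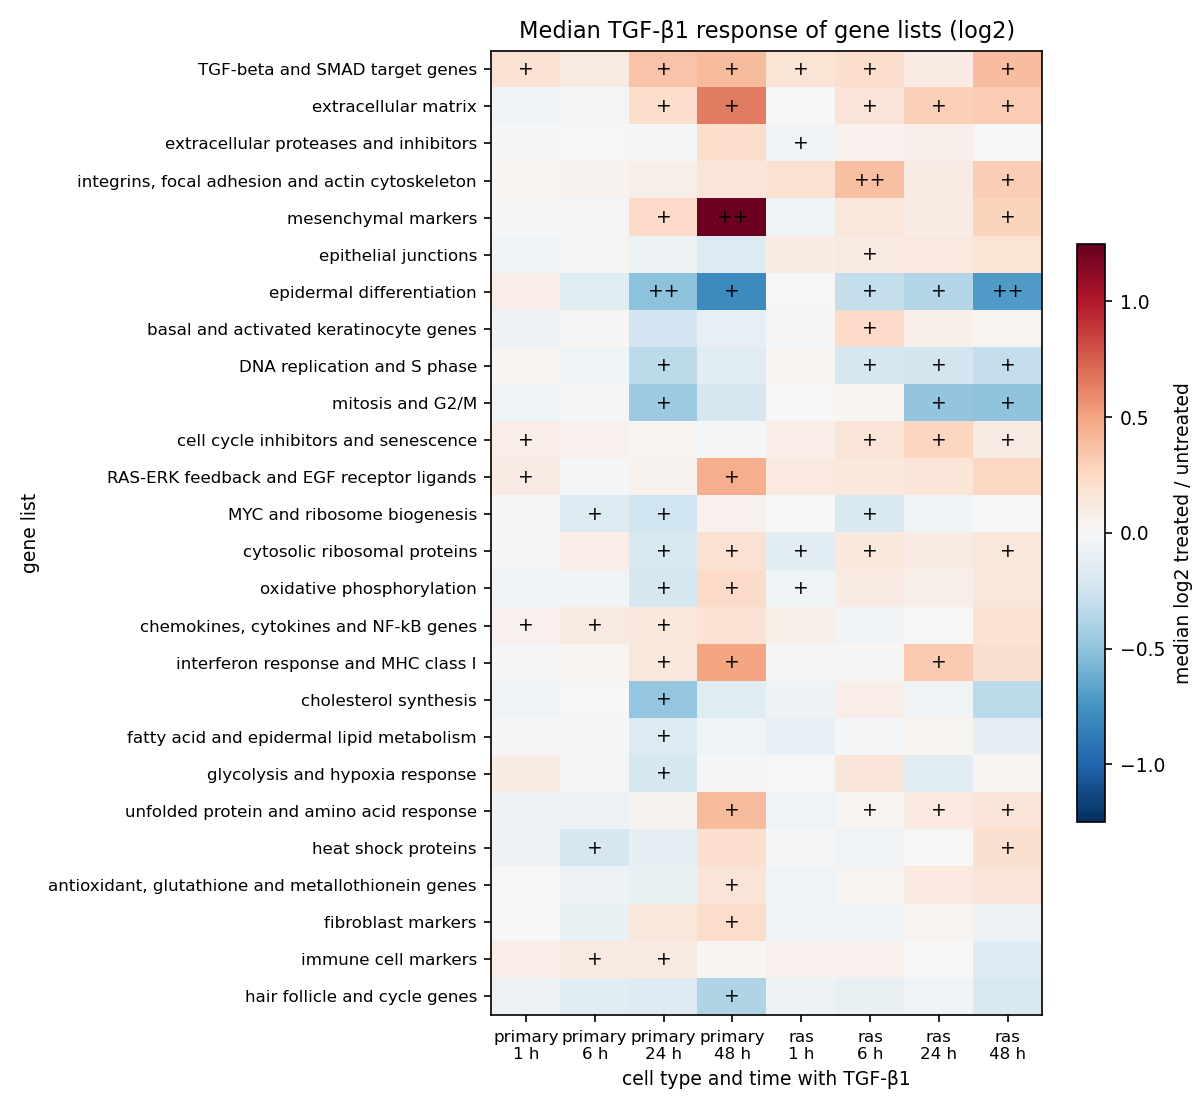
Median log2 response of 26 gene lists (vertical axis) in each cell type and time (horizontal axis), with red for higher and blue for lower in treated cells; + marks lists called with a preset correlation and ++ those also called with an estimated one. The ++ marks are the integrin and actin list in ras cells at 6 h, mesenchymal markers in primary cells at 48 h, and epidermal differentiation in primary cells at 24 h and ras cells at 48 h.

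The calls of primary and ras cells overlapped. At 48 h 91 genes rose and 48 fell in both, where independent lists would share 8.64 and 4.99, and 0 went opposite ways. At 24 h 17 rose and 45 fell in both, against 1.19 and 6.00, and 1 gene went opposite ways. Part of this excess may come from a dye bias that both share, and from untreated RNA if arrays shared it.

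Few genes were called as different between the responses of ras and primary cells, which does not show that the responses were alike. Of simulated changes of 1 on the log2 scale in ras cells, these contrasts found 40.7%, 63.0%, 48.4% and 27.8% at 1, 6, 24 and 48 h. They gave 6, 12, 19 and 94 false calls in the same simulated sets. At 24 h the rise of Ctla2a was larger in ras cells by 1.70 (SE 0.34, adjusted p = 0.0228) and that of Mtg2 by 1.28 (SE 0.22, adjusted p = 0.00584). Sprr2a1 fell less, by 1.32 (SE 0.26), with means of -1.14 in ras and -2.45 in primary cells. Pdgfc, a platelet-derived growth factor gene, was lower in ras cells by -2.10 (SE 0.39), with means of -0.99 and 1.11. The 4 calls lie within the range of 0 to 12 in simulated data with no change. At 48 h 3 genes were higher in ras cells, Lgals7, Exosc6 and Ptp4a3, and 15 were lower. The lower ones included Gng2 by -3.37 (SE 0.75), the collagen-modifying gene Crtap by -2.30 (SE 0.51), S100a4 by -2.13 (SE 0.40), Timp1 by -2.06 (SE 0.45), Lox by -1.59 (SE 0.34), Lyz2 by -1.63 (SE 0.33) and Twist1 by -1.21 (SE 0.28). For S100a4 the means were 0.25 in ras and 2.38 in primary cells. The ras 48 h arrays were uneven: Timp1 was at 1.48 and 1.70 on replicates 1 and 3. It was at -0.86 and 0.10 on replicates 2 and 4, against 2.21 to 3.11 on the primary arrays. The 48 h split with reversed arrays turned was 20 up and 20 down without and 15 up and 32 down with a dye term. With reversed arrays as deposited and both orientations weighted equally it was 15 up and 11 down, with 0 of the 18 calls shared, and with a dye term instead 0 genes were called. At 1 h and 6 h limma called 0 genes, with 371 and 409 features at an unadjusted p under 0.05. The 6 h count was 64 with array weights, 46 with both orientations weighted equally and 1 with arrays scaled to 1 spread.

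Of 132 list tests of these differences 18 were called, and 1 held with an estimated correlation. At 6 h the integrin and actin list was higher in ras cells, with 30 of 31 members positive, 0 called (0 adjusted over the list alone), a median of 0.40 and adjusted p = 0.123 with an estimated correlation. The chemokine, cytokine and NF-κB list was lower in ras cells, with 0 of 27 members called (1 adjusted over the list alone), a median of -0.19 and adjusted p = 0.00927 with an estimated correlation. At 48 h the list of mesenchymal markers was called lower in ras cells, with 2 of 16 called (4 adjusted over the list alone), a median of -0.86 and adjusted p = 0.112 with an estimated correlation, as was the matrix list, with 3 of 42 called (1 up and 6 down adjusted over the list alone), a median of -0.31 and adjusted p = 0.467 with an estimated correlation. Fibroblast markers moved the same way, with 2 of 10 called (2 adjusted over the list alone) and adjusted p = 0.0967 with an estimated correlation. The 18 calls at 48 h are fewer than the median of 66.5 in simulated data with no change, and fitted on their own groups both the 24 h and the 48 h comparison gave 0 calls. The 48 h count was 55 and 80 without primary replicates 1 and 5, 1, 29 and 2 without ras replicates 2, 3 and 4, and the 24 h count 1 without ras replicate 1 or 7 or primary replicate 1 or 3 and 2 without ras replicate 2 or 3. Mtg2 kept its call whichever single array was left out, and the other genes named here lost theirs without 2 or more single arrays (adjusted p up to 0.65, for Crtap). With arrays scaled to 1 spread the 24 h split was 1 up and 0 down, and with array weights 105 up and 30 down.

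Between 6 h and 48 h the response of primary cells shifted towards matrix genes, with 165 genes higher and 79 lower at 48 h. Fbln5 was higher by 2.62 (SE 0.44, adjusted p = 0.00025), with means of 0.01 at 6 h and 2.63 at 48 h. Gng2 was higher by 3.43 (SE 0.67) and Crtap by 2.60 (SE 0.46), with calls that ended without primary 48 h replicates 1 and 2 in turn (adjusted p = 0.0972 and 0.0573). The neuropeptide gene Tac1 (-4.76), 2410022M11Rik (-4.03) and Zfp444 (-3.35) were lower, with calls that ended without single arrays (adjusted p up to 0.468, 0.445 and 0.438). Of the 42 matrix genes 10 were higher (19 adjusted over the list alone) and of the 16 mesenchymal markers 6 (7 adjusted over the list alone), with adjusted p = 0.046 and 0.0335 with an estimated correlation. All 10 fibroblast markers were positive in this contrast, with 3 called (3 adjusted over the list alone) and adjusted p = 0.139 with an estimated correlation. In ras cells Sprr2a1 was lower at 48 h by -1.78 (SE 0.28, adjusted p = 0.00139), Fabp5 was lower by -1.60 (SE 0.31), and 1 unnamed probe was higher. The epidermal differentiation list was lower at 48 h in ras cells, with 2 of 13 called (3 adjusted over the list alone) and adjusted p = 0.0335 with an estimated correlation. Simulated data with no change gave medians of 54.5 calls in primary and 14 in ras cells, and fitted on its own groups the primary contrast gave 62. The primary count was 194 without primary 6 h replicate 4 and 131 without primary 48 h replicate 2, and the ras count was 1 without ras 6 h replicate 2, 3, 4 or 7 or ras 48 h replicate 3 and 13 without ras 48 h replicate 4; the call of Fabp5 ended without 6 of 11 arrays (adjusted p up to 0.105). With arrays scaled to 1 spread the ras split was 1 up and 0 down.

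The Smad3 arrays ask which part of the 48 h response needs Smad3. The Smad3 probe had ratios of treated over untreated RNA within a genotype of -0.84 and -2.79 in wild type and knockout primary cells and -0.31 and -0.68 in ras cells, which does not check the genotype. Clu was up in all 4, at 2.01 in wild type and 1.84 in knockout primary cells and 2.38 and 1.74 in ras cells. Skil was at 1.18 and 1.15 in primary and 0.56 and 0.51 in ras cells. Csf1 stood at 1.33 in wild type and -0.76 in knockout primary cells, and Defb1 at -1.23 and 0.76, with 1 array each and no test. Over the 766 genes called in Balb/c primary cells at 48 h, the slope on the Balb/c values was 0.198 in wild type and 0.107 in knockout cells, with 69.5% and 62.9% of genes of the same sign. With arrays scaled to 1 spread the knockout slope was 0.0607. Over the 312 genes called in ras cells the slopes were 0.252 and 0.245, with 76.6% and 73.7%. The genes were selected for large Balb/c values, some resting on single arrays, which lowers all these slopes. The wild type arrays themselves followed the Balb/c values only in part, with 1 array for each genotype and cell type. The slopes, called shares further below, therefore do not measure the part of the response that needs Smad3. Each list's median signed value lay above all 10000 random lists of the same size. The random lists took genes as independent. Treated RNA carried Cy5 on all these arrays, so a dye bias of each gene could give shared signs too. Within these single arrays Ccl7 was at -0.16 in wild type and -0.11 in knockout primary cells, against 3.07 in Balb/c cells.

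Knockout minus wild type, averaged over both cell types with 1 array each, was called for 155 genes, 39 higher and 116 lower, with the spread taken from the other groups. The split with reversed arrays turned was 42 higher and 29 lower without and 33 higher and 30 lower with a dye term. It was 25 higher and 72 lower with all arrays as deposited and a dye term, 49 and 93 with both orientations weighted equally, 100 and 258 with array weights and 18 and 36 with scaled arrays. The turned settings also turned the reversed knockout arrays, which as deposited correlated at 0.479 and 0.403 with the other array of their group. They thus set each knockout pair against itself. In the reported fit the SEs and calls hold no spread between arrays of any Smad3 group, so they do not show a Smad3 effect. The largest were single values: Zfp362 was lower by -7.36 (SE 0.32), from 5.26 and 1.09 on the wild type arrays to -3.28 and -5.09 on the knockout arrays. Gsta3, a glutathione transferase gene, was lower by -5.04 (SE 0.41) and Thap4 by -4.78 (SE 0.57), and Nr5a2 and Tmem179b by -4.38 and -4.19. The last 2 came mainly from ras cells, with 5.76 and 2.75 on the wild type and -1.73 and -5.39 on the knockout array, against -1.22 and -0.46 and -2.49 and -0.71 in primary cells. Gsta3 also differed more in ras cells, from 2.87 in wild type to -5.12 in knockout, against 2.08 to -0.003 in primary cells. Thap4 differed more in primary cells, from 2.96 to -4.53, against 0.48 to -1.59 in ras cells. Serbp1 was higher by 4.75 (SE 0.42), mainly from primary cells, with -1.73 in wild type and 6.18 in knockout, against -0.57 and 1.02 in ras cells. Rgs5, 1700012B09Rik, Foxd1 and Slc26a3 were higher by 4.10, 3.77, 3.54 and 3.52. Rgs5, 1700012B09Rik and Slc26a3 rested mainly on the knockout primary array (7.01, 5.02 and 5.13, against -0.29, 0.31 and -0.29 on the knockout ras array), and Foxd1 on the wild type ras array (-4.65). Mitosis genes were higher in knockout cells as a list, with 0 of 43 called (1 up and 2 down adjusted over the list alone), a median of 0.44 and adjusted p = 0.526 with an estimated correlation. With values beyond 4 in size as missing the count was 96, and with arrays scaled to 1 spread it was 54.

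The 5 reversed Balb/c arrays, left out of the reported fit, held the opposite sign for Clu and Sprr2a1. Clu was at -2.13 in ras cells at 6 h, -2.41 in ras cells at 24 h, -2.18 and -1.71 in primary cells at 48 h and -0.58 in ras cells at 48 h. Sprr2a1 was at 0.74, 1.18, 4.21, 3.00 and 3.20 on the same arrays. With reversed arrays entered as deposited and both orientations weighted equally, Sprr2a1, Sprr1a and Ppl at 48 h changed sign, and Clu and Skil in ras cells at 6 h went to -0.00343 and -0.0432. A true response would cancel in this way if the reversed arrays had not been turned. With the reversed arrays turned and no dye term, 0 of 248 values of named genes changed sign, 196 kept their side of the threshold, 50 became weaker and 2 stronger. With a dye term as well, 161 kept it, 84 became weaker and 3 stronger, and with all arrays as deposited and a dye term 32 kept it, 209 became weaker and 7 changed sign. Primary cells at 1, 6 and 24 h and ras cells at 1 h had 0 reversed arrays. Without a dye term their values could hence not change sign. In the other Balb/c groups the Cy5 arrays, on which the genes were called, outnumber the reversed ones. The 0 of 248 is therefore no test of the sign.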

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

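All tests of explanations below, including their gene sets and the regrouping of arrays, were chosen only after results had been seen.

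In 147 searches for an array far from the others of its group 15 were found, where chance gives about 1 in 20. In primary cells at 24 h replicate 6 stood apart for Sox11 at 3.20 (others 0.61 to 1.21), Pdgfb at 2.59 (0.57 to 1.03), Thbs1 at 2.07 (0.30 to 0.96), Serpinh1 at 1.29 (0.12 to 0.50) and Cldn4 at 0.10 (0.55 to 0.81). In ras cells at 6 h replicate 6 stood apart for Cxcl5 at -0.35 (others -2.29 to -1.51), Skil at -0.005 (0.82 to 1.27) and Ccn1 at -0.004 (0.72 to 1.16), and its median absolute deviation was 0.55 (others 0.198 to 0.283). Also in ras cells at 6 h Tmprss4 was at -4.74 on replicate 4 (others -1.08 to -0.55) and Pdlim7 at 2.17 on replicate 7 (0.56 to 1.10). Ier3 was at -0.32 on ras 1 h replicate 5 (others -1.16 to -0.94) and Sprr1a at -0.16 on ras 24 h replicate 6 (-1.78 to -1.51). In ras cells at 48 h Hif1a was at -7.02 on replicate 1 (others -1.26 to -0.35) and Id1 at -0.08 on replicate 4 (-1.96 to -1.80).

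Differences between the responses of ras and primary cells were tested as contrasts. At 24 h they were 1.70 for Ctla2a, 1.32 for Sprr2a1, 1.28 for Mtg2 and -2.10 for Pdgfc. At 48 h they were 1.49 for Lgals7, 1.43 for Exosc6 and 1.15 for Ptp4a3, and on the lower side -3.37 for Gng2, -2.30 for Crtap, -2.13 for S100a4, -2.06 for Timp1, -1.77 for Ankrd1, -1.71 for Crabp1, -1.65 for Ccl7, -1.63 for Lyz2, -1.59 for Lox, -1.44 for Mfap5 and -1.21 for Twist1. Between 6 h and 48 h the response of primary cells differed by 3.43 for Gng2, 2.62 for Fbln5, 2.60 for Crtap, -4.76 for Tac1, -4.03 for 2410022M11Rik and -3.35 for Zfp444, and that of ras cells by -1.78 for Sprr2a1 and -1.60 for Fabp5. Knockout minus wild type of Smad3 differed by 4.75 for Serbp1, 4.10 for Rgs5, 3.77 for 1700012B09Rik, 3.54 for Foxd1, 3.52 for Slc26a3, -7.36 for Zfp362, -5.04 for Gsta3, -4.78 for Thap4, -4.38 for Nr5a2 and -4.19 for Tmem179b.

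The 5 reversed Balb/c arrays, which the reported fit left out, were compared with the called genes. The share of called genes with the sign opposite to the other arrays was 92.9% on ras 6 h replicate 5, 46.3% on ras 24 h replicate 4, 58.6% and 62.7% on primary 48 h replicates 3 and 4, and 40.1% on ras 48 h replicate 5. The genes were called on the other arrays, so these give no reference level, and no chance value was computed for unrelated signs.

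Reversed arrays that hold Cy5 over Cy3 ratios could give opposite signs. Among genes called the same way in another response too, the opposite share was 96.9%, 83.4%, 67.1%, 67.1% and 47.3%, with a median of 67.1%, which leaves this open. A dye bias of each gene could do so as well, and if constant it would be present at 1 h. The slopes of 1 h values on later values over the called genes were 0.344 at most. This cannot decide, since the genes were selected for large later values, some of which rest on single arrays, and this lowers the slope in any case. No biological explanation was tested, since the dye is the only difference the labels give.

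Ras cells had more calls than primary cells at 24 h, 936 against 121. A single wide array may add calls, but without ras 24 h replicate 1 there were still 273, which argues against that array alone as the whole cause. Array width in general stays open. Replicate 3 had an SD of 1.19, and with arrays scaled to 1 spread the counts were 383 in primary and 299 in ras cells. Unequal array quality goes with the counts, since array weights gave 562 in ras and 835 in primary cells. A stronger response of ras cells stays open: over 63 genes called in both, the median size in ras minus primary was -0.10, and with array weights it was 0.13 over 152 genes.

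Of 18 genes called as different between ras and primary cells at 48 h 15 were lower in ras cells, among them 3 of 42 matrix genes and 2 of 16 mesenchymal markers. Neither list held with an estimated correlation (adjusted p = 0.467 and 0.112), and simulated data with no change gave a median of 66.5 calls. A higher share of unchanged fibroblasts in treated primary cultures could raise these genes, and all 10 fibroblast markers had a median of 0.23 (SD 0.88) in primary cells, below the smallest (1.28) and the median (2.20) of the rises of the 15 genes lower in ras cells by more than their SD. The markers as a set thus rose less than these genes, but this cannot decide on unchanged fibroblasts. The 15 genes were selected as called differences, and Twist1, which sets the smallest rise, and Mfap5 are themselves among the 10 markers. In addition, 3 of the markers rose. Fibroblasts that respond themselves stay open and were not tested. A mesenchymal shift of keratinocytes that is weaker in ras cells also stays open, with a median difference of -0.68 over 12 other mesenchymal markers (0.87 in primary, 0.33 in ras). Chance is not excluded either, since 8 of 35 regroupings of the arrays gave as many calls as the 18 found.

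Each count was also compared with regroupings, in which signs of arrays or labels were exchanged; the real grouping counts as 1. As many calls were found in 3 of 32 for primary cells at 1 h, which does not exclude chance, 3 of 64 at 6 h, 1 of 32 at 24 h and 1 of 4 at 48 h, where the regroupings are too few to tell. For ras cells it was 1 of 32 at 1 h, 1 of 64 at 6 h, 1 of 32 at 24 h and 1 of 8 at 48 h, again too few. For ras minus primary the real count was 0 at 1 h and at 6 h, so all 100 of 100 had as many by construction and nothing was tested; it was 3 of 100 at 24 h and 8 of 35 at 48 h, and for 48 h minus 6 h it was 4 of 100 in primary and 1 of 100 in ras cells. Regroupings reached up to 25 calls for primary cells at 6 h (1 real), 389 for ras minus primary at 6 h (0 real), 107 at 48 h (18 real) and 584 for 48 h minus 6 h in primary cells (244 real), which points to a structure of the samples that was not tested. The 25 calls came from exchanging the sign of primary 6 h replicate 4 alone, and the 584 from setting primary 6 h replicates 1, 3 and 4 apart, of which replicate 1 is among the widest arrays (SD 1.68). The 107 calls came from grouping ras 48 h replicates 1 and 3 with primary 48 h replicates 1 and 2.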

How the results depend on the processing

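The settings called added were chosen only after seeing the data, and where a value moved the cause was not tested. The depth behind each ratio is unknown, since no spot intensity was used. Leaving out a Smad3 array left the knockout contrast without an estimate. The missing value filters changed nothing, and Cy5 arrays alone or no dye term equal the reported fit.

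With arrays scaled to the same median absolute deviation, calls at 1, 6, 24 and 48 h were 2, 18, 383 and 429 in primary and 17, 378, 299 and 206 in ras cells. Ras minus primary gave 1 at 6 h, 1 at 24 h and 0 at 48 h, 48 h minus 6 h gave 94 in primary and 1 in ras cells, and Smad3 54. The Smad3 share in knockout primary cells was 0.0607. With array weights, primary cells had 4, 16 and 835 calls at 1, 6 and 24 h and ras cells 91, 1203 and 562; ras minus primary gave 64 at 6 h and 135 at 24 h, 48 h minus 6 h 385 and 8, and Smad3 358. With only the groups compared, primary cells had 0, 0, 10 and 0 calls, ras cells 0 at 1 h, 3 at 24 h and 0 at 48 h, ras minus primary 1, 0 and 0 at 6, 24 and 48 h, and 48 h minus 6 h in primary cells 62. With the upload block as a random block, primary cells had 0 at 1 h and 0 at 6 h and ras cells 98, 505 and 111 at 6, 24 and 48 h.

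With both dye orientations weighted equally and reversed arrays as deposited, ras cells had 67, 2 and 76 calls at 6, 24 and 48 h, ras minus primary 46 at 6 h, and 48 h minus 6 h 33 in primary and 71 in ras cells. With all arrays as deposited and a dye term (added), primary cells had 0 at 6 h and 0 at 24 h, ras cells 0, 0, 1 and 32, ras minus primary 0 at 24 h and 0 at 48 h, 48 h minus 6 h 10 and 0, and Smad3 97. With reversed arrays turned and no dye term (added), primary cells had 0 at 1 h, ras cells 413 at 24 h and 71 at 48 h, ras minus primary 0 at 24 h and 40 at 48 h, Smad3 71, and the list shifts of differences were 29. With reversed arrays turned and a dye term (added), primary cells had 0, 13 and 326 at 1, 6 and 24 h, ras cells 88, 152 and 41 at 1, 24 and 48 h, ras minus primary 2 at 24 h and 47 at 48 h, Smad3 63, and list shifts were 104 for responses and 36 for differences. With values beyond 4 missing (added), Smad3 gave 96, its shares were 0.258 in wild type primary and 0.334 in wild type ras cells, and list shifts of differences were 28. Without the 2 widest arrays (added), primary cells had 0 at 6 h, ras cells 240, 316 and 484 at 6, 24 and 48 h, and ras minus primary 1 at 24 h and 30 at 48 h.

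Leaving out each array in turn gave 0 to 1, 0 to 9, 60 to 131 and 279 to 763 calls in primary cells at 1, 6, 24 and 48 h, and 0 to 8, 62 to 181, 273 to 1067 and 54 to 491 in ras cells. Ras minus primary gave 0, 0, 1 to 5 and 1 to 80, 48 h minus 6 h 131 to 361 in primary and 1 to 13 in ras cells, and list shifts 61 to 72 for responses and 17 to 24 for differences. The Smad3 shares ranged over 0.151 to 0.208 and 0.0736 to 0.134 in wild type and knockout primary cells, and 0.206 to 0.259 and 0.210 to 0.251 in ras cells. Of 226 calls of named genes 94 were kept throughout and 132 ended at least once. Without primary 48 h replicate 2, Krt16 turned from -1.18 to 0.0853, and without replicate 5 it was at -1.84.

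Replicate numbers shared by primary and ras arrays were not taken as pairs, since the preset rule asked for a correlation over 0.1 in every pair. With the replicate block the counts stayed at 121 and 766 in primary cells at 24 and 48 h, with a consensus correlation of -0.000439, and over 19 such pairs the median correlation was 0.048 (-0.23 to 0.39), with 5 over 0.1 and 5 matching their own number best, so that some pairs stay open.

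With both orientations weighted equally, genes changed sign. If the authors had not turned the reversed arrays, a true response cancels by construction in this setting. The values below therefore cannot tell how stable a response is. In ras cells at 6 h Clu was at -0.00343, Pdgfb -0.0504, Skil -0.0432, Ccn1 -0.11, Mdm2 -0.0141, Myc 0.00314, Nop58 0.15 and Srm 0.19. At 24 h Cdkn2b was at -0.0708, Plau -0.0115, Sprr1a 0.25 and Sprr2a1 0.0236, and at 48 h Sprr2a1 0.49, Sprr1a 0.42, Ppl 0.0816, Ccn1 -0.15, Thbs1 -0.0119 and Tnf -0.0729. In primary cells at 48 h Id3 was at 0.0332, Serpinb2 0.58, Fabp5 0.52, Sprr2a1 0.64, Sprr1a 0.17, Ppl 0.23, Il18 0.13, Krt19 0.0259, Trp63 0.25 and Cldn1 0.0213. Sprr2a1 was at 0.34 for 48 h minus 6 h in ras cells, and for ras minus primary at 48 h Ankrd1 was at 0.47, Crabp1 0.28, Lyz2 0.0367 and Twist1 0.20. With all arrays as deposited and a dye term, Sprr2a1 was at 0.27 in ras cells at 24 h, and in primary cells at 48 h Serpinb2 was at 0.30, Fabp5 0.34, Sprr2a1 0.34, Sprr1a 0.0632, Ppl 0.10 and Trp63 0.0662.

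Lists that turned with all arrays as deposited and a dye term were interferon genes in primary cells at 24 h (median -0.0221), matrix genes in ras cells at 6 h (-0.0346), and epidermal differentiation in ras cells at 6 h (0.20), at 24 h (-0.0738, where the direction of the test turned) and in the Smad3 contrast (-0.014). With reversed arrays turned and no dye term, ribosomal genes were at -0.19 and oxidative phosphorylation at -0.14 in primary cells at 48 h, oxidative phosphorylation at -0.15 for 48 h minus 6 h, and in the Smad3 contrast basal keratinocyte genes at -0.21, ribosomal genes at -0.14, oxidative phosphorylation at -0.19 and glycolysis at -0.0605. The Smad3 values here rest on turned knockout arrays, which correlated positively with their partners as deposited. With a dye term as well, ribosomal genes were at -0.24, oxidative phosphorylation at -0.20 and antioxidant genes at -0.0555 in primary cells at 48 h. In ras cells ribosomal genes were then at -0.11 at 6 h and -0.10 at 48 h, and unfolded protein response genes at -0.13, -0.0474 and -0.0511 at 6, 24 and 48 h.

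Of 248 values of named genes, all kept their direction and side of the threshold with the replicate block, 247 without centring, 246 with single probes, 234 without the widest arrays, 228 with array weights, 215 with the upload block and 195 with scaled arrays. With reversed arrays turned 196 did without and 161 with a dye term, and 32 did with all arrays as deposited and a dye term, where 7 reversed. With both orientations weighted equally 15 did, 147 were weaker and 33 reversed, and with only the groups compared 43 did and 195 were weaker, since not every value exists in these fits.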

Other observations

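The gene lists and their tests were planned, but which of their results and genes are given here was chosen only after results had been seen.

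Genes of chemokines and cytokines went both ways at 48 h, and their list was not called. Ccl2, a monocyte chemokine gene, rose by 2.67 (SE 0.30) in primary and 1.38 (SE 0.26) in ras cells, and Tnf rose by 1.27 (SE 0.22) in ras cells. Il18 fell in both, to -1.50 (SE 0.34) and -1.30 (SE 0.29), as did Il33. Of the 27 list members 5 rose and 4 fell in each cell type (8 and 6 in primary, 6 and 4 in ras cells adjusted over the list alone; adjusted p = 0.189 and 0.19). Interferon response genes rose in primary cells at 48 h, 7 of 27 (9 adjusted over the list alone), among them Ifit3 by 1.45 (SE 0.22), with adjusted p = 0.0876 with an estimated correlation. In ras cells at 24 h 7 rose and 1 fell (11 and 1 adjusted over the list alone), among them Usp18 by 1.22 (SE 0.25) and Oasl2 by 0.92 (SE 0.21), with adjusted p = 0.199 with an estimated correlation.

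Hmox1, which encodes haem oxygenase, rose by 1.56 (SE 0.25) in primary cells at 48 h, and Trp63, a basal keratinocyte transcription factor, fell by 1.01 (SE 0.20). Of 31 antioxidant genes 5 rose (7 adjusted over the list alone), with adjusted p = 0.38 with an estimated correlation.

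Of the 33 lists, 7 were called in no response: TGF-β and BMP pathway components, simple keratins, immediate early genes, apoptosis, and melanocyte, endothelial, and muscle and adipocyte markers. The lowest adjusted p of these over 8 responses were 0.077, 0.145, 0.14, 0.322, 0.19, 0.171 and 0.118.

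On the Smad3 arrays of ras cells the Tgfb1 probe was at 0.26 in wild type and 5.69 in knockout cells, and Sprr2a1 was at 0.45 and 0.55, against -2.23 in Balb/c ras cells at 48 h. Each Smad3 value comes from 1 array with no test. In primary cells Tgfb1 was at -0.38 in wild type and -0.75 in knockout cells, so the high value stands on a single array.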
